A study of Mus musculus with 24 samples.

How the data were processed

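Polyadenylated RNA of mouse left ventricle was sequenced in 24 libraries. Per the labels, the DKO mice had lost Rhot1 and Rhot2 in cardiomyocytes before birth, and their controls had not. Each library was labelled day 1 or day 7 of age, which gave 4 groups of 6 libraries. The labels call the source cardiomyocytes, while the extraction protocol names left ventricular tissue, so other cells of the ventricle were included. Each library carried its own animal or library name, and no name was shared between groups, so no pairing was used. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries. Per the labels' protocols, libraries were made with a low-input cDNA kit, which does not mark strand, from 100 ng of total RNA.

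The deposited values were raw counts of reads per gene, as whole numbers, with 1 column per library and no pooling. Per the submitters' processing notes, STAR 2.4.2a, bcl2fastq and the genome build GRCm39 were used. The counting tool, its treatment of overlapping genes and the annotation release were not given in the sources used here. The table held 39396 genes, of which 12380 were at 0 counts in all 24 libraries, among them 2641 of 21210 protein-coding genes. Another annotation, GENCODE M21 on GRCm38, was used to ask which genes have exonic bases inside other genes. Inside meant within the span of another gene, introns included, on either strand. All 39396 identifiers matched that annotation, which also gave the gene spans for the length trend and the chromosomes for Y-linked genes. Of 1347 protein-coding genes whose exonic bases all lie inside other genes, 1078 (80.0%) were at 0. This compares with 1502 of 13831 (10.9%) of those with no exonic base inside another gene. Genes at 0 for this or another reason cannot be reported. They include Rhot2, the cardiac and skeletal actins Actc1 and Acta1, Tnnc1, Pln, Cox4i1, Cox6a2, Cpt1b, Myom1 and Srf. Myh7 and Nppa had 75.3% and 69.3% of their exonic bases inside other genes, so their counts may cover part of each transcript, and their levels should be compared only between groups. None of the 37 genes of the mitochondrial genome had counts, whereas nuclear copies of mitochondrial genes took 4.30 to 7.09% of counts in libraries labelled day 1 and 2.17 to 3.30% in those labelled day 7. Genes that share reads with near-identical copies (skeletal myosin heavy chains, vomeronasal receptors, ribosomal protein genes, alpha globins, processed pseudogenes) are uncertain, as the treatment of reads matching several places was not given. For the same reason, counts on nuclear copies of mitochondrial genes do not show which genome the reads came from. For 52 genes the symbol was blank, and these stayed in the tests under their identifiers.

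Total counts ran from 30318018 to 45806171 in libraries labelled day 1 and from 17334498 to 30453874 in those labelled day 7. All replicate pairs differed by more than sampling noise (chi-square per degree of freedom of at least 5.69), so no library was treated as a repeat of another. Genes were kept by filterByExpr over the 4 groups (minimum count 10), which left 17352 genes for every fit. Counts were scaled by TMM (trimmed mean of M values) and tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The effect of the genotype was fitted within each labelled age over 12 libraries. The difference of that effect between the labelled ages, and the effect of labelled age within each genotype, were fitted over all 24 libraries. Levels are CPM, the library-size scaled counts of edgeR, after TMM, as mean ± SD with n = 6, and fold changes are log2 with their standard error (SE). The SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. It is therefore approximate, above all for genes with few counts in a group.

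Before the data were examined, 54 gene lists were fixed, 38 of pathways or gene groups and 16 of cell type markers. A list, the genes of the mitochondrial genome, had no member to test. The other 53 were tested with camera from limma 3.58.1 with a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. After the results were seen, an exact permutation test of each list's mean log2 CPM (prior count 2) over the 924 splits of 12 libraries into 6 and 6 was added, because random splits of the libraries gave as many lists with the preset correlation. Calls within a list are given over all genes and adjusted over the list alone. Shares of isoform pairs were compared by exact two-sided permutation tests over 924 splits, adjusted by Benjamini-Hochberg. To ask where the DKO libraries lay along the change between the labelled ages, genes changing with labelled age were called with 3 of the 6 controls of the age compared, and the DKO libraries were compared with the other 3 over 84 splits. All 20 choices of the 3 controls were run.

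Genes were named by a rule written before the data were examined. It took Rhot1 and Rhot2, then the 10 largest rises and 10 largest falls per genotype comparison among genes past the threshold with at least 10 CPM in either group and every DKO library on the same side of the control mean. It left out Xist, Y-linked genes, haemoglobin genes and gene models without an ordinary symbol. It also took up to 4 members per list with the smallest p among those past the threshold, or 2 where none passed. For the difference between labelled ages and for age in controls it took the 5 largest changes each way. Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Tnni1, Tnni3, Gdf15, Fgf21, Atf4 and Ppargc1a were always included. Some genes that the rule named are not reported here. Other genes named in the text were chosen after their values were seen, and this is said where they appear.

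The fits were tested on simulated counts drawn from the real genes' means and library sizes. Changed genes were picked among those with a mean over 1 CPM, so recovery below that level was not tested. Genes were drawn independently of each other, unlike in real libraries. Within each labelled age the dispersion was estimated without the genotype in the model, so it includes the genotype difference. Of 100 genes changed by 1 on the log2 scale, 86 were recovered at each labelled age, and of 100 changed by 2, 98 were recovered. There were 5 false calls among 17352 genes in the labelled day 1 design and 10 in the labelled day 7 design. For the difference between labelled ages, 87 and 99 of 100 were recovered with 8 false calls.

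Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom with sample quality weights, no filter and a stricter filter (1 CPM on average), mitochondrial and haemoglobin genes left out, all 24 libraries in 1 fit, centring on the median fold change, and each library left out in turn. As no gene of the mitochondrial genome had counts, leaving out mitochondrial and haemoglobin genes dropped haemoglobin genes alone. Nuclear copies of mitochondrial genes stayed in. Others were chosen after seeing the data: pseudogenes left out, a length trend removed per library, atrial transcripts or Y transcripts as a covariate, and libraries with Y transcripts, controls with over 50 CPM of Myl7, or DKO m1124 and m1128 left out. The length trend was taken over genomic span, introns included, in protein-coding genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and permutation tests of correlations used 100000 resamples.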

Results

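Gene expression was measured by RNA sequencing of left ventricular tissue from newborn mice. In the mutants (DKO), per the labels, the genes Rhot1 and Rhot2 had been deleted in cardiomyocytes before birth. These genes code for the RHOT (Miro) proteins, anchors of the outer mitochondrial membrane that couple mitochondria to molecular motors. There were 6 control and 6 DKO libraries labelled day 1, and 6 control and 6 DKO libraries labelled day 7. Total counts per library were 36145645 to 45806171 in controls and 30318018 to 37967935 in DKO labelled day 1. Among libraries labelled day 7 they were 17334498 to 27272982 in controls and 22345262 to 30453874 in DKO. Y-linked transcripts were taken as present at over 10 CPM of Eif2s3y. By this rule they were present in all 12 libraries labelled day 1 and in 4 of the 12 labelled day 7, 2 of each genotype. The labels of age are used throughout as given, although the genes that change with age, described further on, ran opposite to the known order of heart development.

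The first question was how much RNA of the deleted genes was counted. Counts per gene in ventricular tissue include cells other than cardiomyocytes and do not tell exons apart. The Rhot1 values therefore do not measure how completely the gene was deleted in cardiomyocytes. Rhot1 (ENSMUSG00000017686) was at 158 ± 17 CPM in controls and 119 ± 9.9 CPM in DKO at labelled day 1 (mean ± SD, n = 6). The log2 fold change was −0.42 ± 0.08 (SE, edgeR adjusted p = 0.0011), and all 6 DKO libraries were below the control mean. In libraries labelled day 7 it was at 155 ± 7.4 CPM in controls and 132 ± 11 CPM in DKO. The log2 fold change there was −0.25 ± 0.06 (edgeR adjusted p = 0.087), which did not pass the threshold with edgeR and did pass with DESeq2 (−0.24), with limma-voom (−0.25) and without DKO m1046 (−0.30, adjusted p = 0.021). The difference between the labelled ages was 0.18 ± 0.10 (adjusted p = 0.53). By library, the DKO values of Rhot1 at labelled day 1 were 114, 107, 117, 118, 120 and 136 CPM for DKO 29, 33, 35, 55, 69 and 79. The controls 13, 14, 22, 25, 56 and 62 were at 129, 163, 169, 173, 149 and 165 CPM. Among libraries labelled day 7, DKO m1026, m1046, m1067, m1092, m1124 and m1128 were at 123, 151, 136, 123, 125 and 133 CPM. The controls m1022, m1064, m1066, m1088, m1091 and m1101 were at 144, 158, 156, 164, 149 and 161 CPM. Rhot2 had no counts in any library, so its loss could not be checked.

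The comparison of DKO with control hearts at labelled day 1 asks which transcripts differ between the genotypes the labels give. The values do not show how far RHOT proteins were lost, since Rhot1 RNA remained and Rhot2 was not measured. Of the fixed lists, the integrated stress response, the programme run by the transcription factor ATF4, had the most members past the threshold, all of them rises. Asns, which makes asparagine, rose from 7.39 ± 1.1 to 102 ± 42 CPM (SD, n = 6), a log2 fold change of 3.78 ± 0.28 (SE, adjusted p = 1.9e-06). Phgdh, the first enzyme of serine synthesis, rose by 3.73 ± 0.34 on the log2 scale, and Mthfd2, an enzyme of mitochondrial folate metabolism, rose by 3.31 ± 0.25. The amino acid transporter Slc7a3 rose by 5.56 ± 0.57, and Trib3, a pseudokinase that is a target of ATF4, rose by 3.30 ± 0.35. Genes of the hormones released under mitochondrial stress were also higher: Gdf15 rose by 3.28 ± 0.35, and Fgf21 went from 3 counts in the 6 control libraries together to 589 in the 6 DKO libraries, a ratio of 232 after scaling (95% Clopper-Pearson interval for counting error, 79.0 to 1127.6). Atf4 itself rose by 0.64 ± 0.13 (adjusted p = 0.0026), and Atf5, a factor of the mitochondrial unfolded protein response, rose by 1.59 ± 0.17. Of the 40 members of this list that were tested, 28 rose and 0 fell over all genes tested, and 32 rose and 0 fell when adjusted over the list alone. None fell at an unadjusted p under 0.05 with edgeR, and DESeq2 and limma-voom gave 30 and 31 rises and 0 falls. The median log2 fold change was 0.71, with a camera adjusted p = 9.9e-29, and an adjusted p = 0.109 with an estimated correlation, so the call is lost there. In an exact permutation test of the list's mean over libraries, chosen after the results were seen, the DKO mean was higher by 1.23 (log2, n = 6, p = 0.0021645, the smallest possible, adjusted p = 0.0191).

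**Figure D1:**
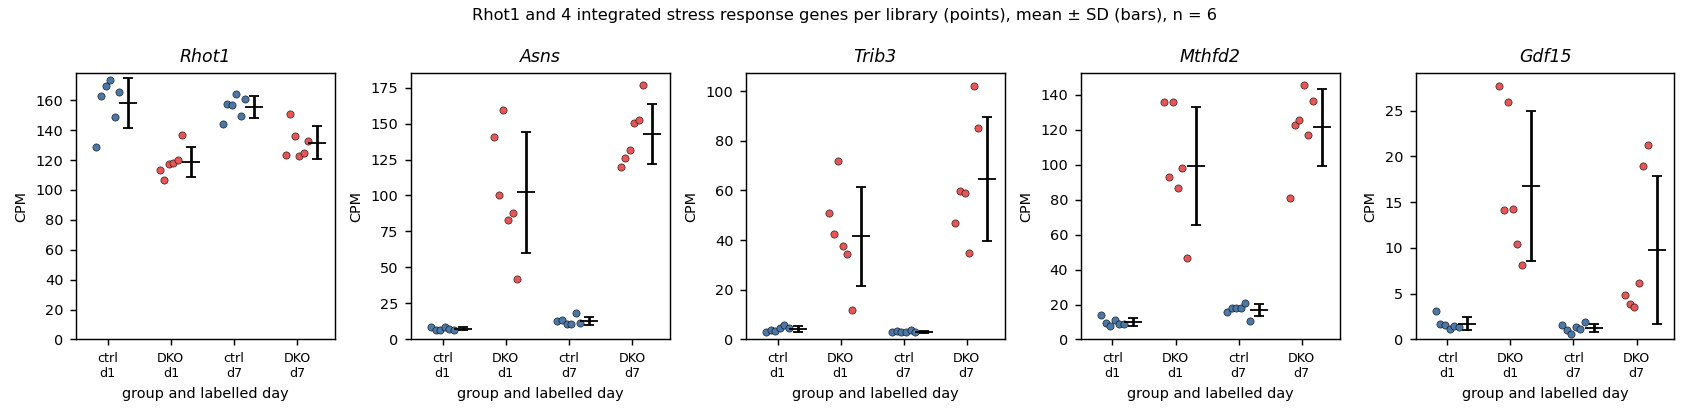
Levels (CPM) of Rhot1, Asns, Trib3, Mthfd2 and Gdf15 in each library (points), with mean and SD (bars, n = 6), in control (blue) and DKO (red) hearts at labelled day 1 and day 7. DKO libraries of labelled day 1 had 114, 107, 117, 118, 120 and 136 CPM of Rhot1, and Asns rose from 7.39 to 102 CPM in them.

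Some genes of cardiac stress also rose at labelled day 1. Nppa, which codes for atrial natriuretic peptide, rose from 34.2 ± 27 to 354 ± 270 CPM (log2 fold change 3.37 ± 0.58, adjusted p = 0.0015), and Nppb, which codes for B-type natriuretic peptide, rose by 1.61 ± 0.36. The stretch-responsive gene Ankrd1 rose by 1.08 ± 0.23, Myc, a transcription factor of cell growth, by 1.43 ± 0.22, and the matricellular gene Ccn2 by 0.99 ± 0.24. The epithelial keratins Krt18 and Krt8 rose by 3.22 ± 0.31 and 3.14 ± 0.42, Krt18 from 6.63 to 62.0 CPM, and were the 2 of 9 epicardial markers that rose, over all genes and adjusted over the list alone, in a list with a median of −0.80 and a mean of 0.24 that camera did not call. The list of cardiac stress and hypertrophy had 8 of 27 members up and 1 down, and 10 up and 1 down when adjusted over the list alone (median 0.23, camera adjusted p = 0.0023, adjusted p = 0.601 with an estimated correlation). Among genes of p53 and apoptosis, 11 of 27 rose and 1 fell over all genes and over the list alone (adjusted p = 0.438 with an estimated correlation). Sesn2, a sestrin that restrains mTORC1 and is also a target of ATF4, rose by 1.21 ± 0.17, and the death receptor gene Tnfrsf10b by 0.54 ± 0.10. Bcl2l11, which codes for the pro-apoptotic protein BIM, fell by 1.01 ± 0.14. When controls with over 50 CPM of the atrial gene Myl7 were left out, which leaves 2 controls, Nppa was at 3.76 (adjusted p = 0.057), so the call ended with the fold kept.

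Some genes of excitation and of the contact between cardiomyocytes fell in DKO at labelled day 1. Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell from 1959 to 1292 CPM (−0.61 ± 0.12, adjusted p = 0.0020). The L-type calcium channel subunits Cacnb2 and Cacna2d1 fell by 0.74 ± 0.09 and 0.55 ± 0.07, while the calcium sensor gene S100a1 rose by 0.63 ± 0.07. Of 26 genes of calcium handling, 1 rose and 10 fell, with the same counts adjusted over the list alone (median −0.21, camera adjusted p = 0.00047, adjusted p = 0.438 with an estimated correlation). Kcnj2, the inward rectifier potassium channel, fell by 1.14 ± 0.16, and the pacemaker channel gene Hcn4 fell by 1.97 ± 0.27. Of 25 ion channel genes, 1 rose and 8 fell, or 9 fell when adjusted over the list alone (median −0.14, adjusted p = 0.424 with an estimated correlation). Atrial markers were lower in the same DKO libraries, by 1.32 in the mean of their list (exact permutation test, adjusted p = 0.0656), and Kcnj3 is a member of that list too. The atrial gene Sln (−4.54) is a member of the calcium handling list and among its falls. The intercalated disc and costamere list, which anchors cells to each other and to the matrix, had 0 of 32 genes up and 11 down both ways (median −0.10, camera adjusted p = 0.00047, adjusted p = 0.438 with an estimated correlation). Its members Ctnna3, Cdh2 and Sgcd, an alpha catenin, N-cadherin and delta-sarcoglycan, fell by 0.64 ± 0.07, 0.47 ± 0.07 and 0.60 ± 0.06. None of its genes rose at an unadjusted p under 0.05 with edgeR, or past the threshold with DESeq2 or limma-voom, and this held for falls of ribosomal genes and rises of atrial genes at this labelled age. The potassium channel gene Kcnj3 fell by 1.51 ± 0.17. Outside the lists, the fibroblast growth factor homologue Fgf14 fell by 1.67 ± 0.15, and the G protein regulator Rgs6 by 1.47 ± 0.13.

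Sarcomere genes moved both ways at labelled day 1. Of 48 tested, 8 rose and 10 fell, or 9 rose and 14 fell adjusted over the list alone, and camera did not call the list. The actin-bundling gene Palld fell by 0.61 ± 0.06, and the Z-disc and thin filament genes Nebl and Tmod1 fell by 0.35 ± 0.07 and 0.28 ± 0.05. Ttn, the giant spring of the sarcomere, and Tnnt2, cardiac troponin T, fell by 0.27 ± 0.05 and 0.35 ± 0.08. Trim54, a ubiquitin ligase of the sarcomere, rose by 1.21 ± 0.18, and the M-band gene Myom2 rose by 0.38 ± 0.09. The cardiac myosins differed by less than the test could call, with Myh6 at −0.05 ± 0.07 (adjusted p = 0.72) and Myh7 at 0.14 ± 0.06 (adjusted p = 0.14). Tnni1, the fetal troponin I, was at −0.40 ± 0.40 (adjusted p = 0.56), and Tnni3, the adult form, at −0.19 ± 0.11 (adjusted p = 0.24). Of 17 genes of mature heart isoforms, 1 rose and 5 fell both ways (median −0.10, camera adjusted p = 0.039, adjusted p = 0.807 with an estimated correlation). Of these, the channel genes Ryr2 and Kcnj2 fell and Myom2 rose, with values given here or with their other lists. Fetal heart isoforms had 6 of 16 genes up and 2 down, or 6 and 3 adjusted over the list alone, with a median of 0.09 and a mean of −0.06, and camera did not call the list.

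Other members of the lists fell or rose at labelled day 1. Tbx5, a factor of chamber formation, fell by 0.88 ± 0.10, Gata6 by 0.63 ± 0.09, and Mef2a, a factor of muscle genes, by 0.31 ± 0.06. In the list of growth factor and developmental signalling, 1 of 33 genes rose and 6 fell, or 7 fell adjusted over the list alone (adjusted p = 0.601 with an estimated correlation), and the exact permutation test did not call it (−0.12, adjusted p = 0.162). Lonp1, a protease of the mitochondrial matrix, rose by 0.78 ± 0.11, and the matrix chaperones Hspa9 and Hspd1 rose by 0.44 ± 0.09 and 0.30 ± 0.06. Of 38 genes of mitochondrial chaperones, proteases and import, 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.0093, adjusted p = 0.807 with an estimated correlation). Genes of respiratory complex I did not pass with edgeR, 0 of 34, with 1 at an unadjusted p under 0.05, 0 past the threshold with DESeq2 and 1 fall with limma-voom. Fatty acid oxidation had 6 of 31 genes up and 1 down, also adjusted over the list alone, and was called by the exact permutation test (0.0902, 6 of 6 DKO libraries above the control mean, adjusted p = 0.0313) and not by camera, with Acot2, a mitochondrial thioesterase, up by 0.61 ± 0.09. Of 23 regulators of mitochondrial biogenesis, 0 rose and 5 fell, or 6 fell adjusted over the list alone (median −0.15, adjusted p = 0.630 with an estimated correlation). Thrb, the thyroid hormone receptor beta, fell by 0.82 ± 0.24, while Ppargc1a, a coactivator of mitochondrial genes, was at 0.77 ± 0.30 (adjusted p = 0.095). Glycolysis had 7 of 25 genes up and 1 down, or 11 up and 1 down adjusted over the list alone (median 0.17, adjusted p = 0.754 with an estimated correlation), among them Pgam1 at 0.62 ± 0.09 and Aldoa at 0.38 ± 0.06. Among genes of mitochondrial motility and dynamics, the pathway of the deleted genes, 0 of 37 rose and 1 fell with edgeR, Kif5c, a kinesin heavy chain, by 0.57 ± 0.17, and 0 fell when adjusted over the list alone. At an unadjusted p under 0.05, 1 gene of this list was higher and 3 were lower, and DESeq2 and limma-voom each called 1 fall.

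Some lysosomal and ribosomal genes rose at labelled day 1. Ctsd, a protease of the lysosome, rose by 0.48 ± 0.08, and the list had 10 of 32 genes up and 2 down both ways (median 0.12, adjusted p = 0.438 with an estimated correlation). Of 57 cytosolic ribosome genes, 11 rose and 0 fell, or 26 rose and 0 fell adjusted over the list alone (median 0.20, camera adjusted p = 5.5e-07, adjusted p = 0.807 with an estimated correlation), such as Rps15 at 0.43 ± 0.09. The exact permutation test of list means called the lysosome list (0.15, adjusted p = 0.0191) and did not call the ribosome list (0.22, adjusted p = 0.101). Myosin heavy chains of skeletal muscle rose from low levels, Myh1 by 1.63 ± 0.13 and Myh4 by 1.70 ± 0.14, and the skeletal muscle list had 6 of 10 genes up and 1 down both ways (median 1.32, adjusted p = 0.109 with an estimated correlation). Some transcripts typical of atrial muscle fell: Myl7, the atrial myosin light chain, fell from 119 to 5.63 CPM (−4.41 ± 1.12, adjusted p = 0.020), and Sln, sarcolipin, fell by 4.54 ± 0.93. The atrial list had 0 of 10 genes up and 4 down, or 6 down adjusted over the list alone (median −0.998, adjusted p = 0.411 with an estimated correlation, and −1.32 with adjusted p = 0.0656 by the exact permutation test). Myl7 ranged from 1.34 to 304 CPM among the 6 controls. With only the 2 controls under 50 CPM of Myl7, Sln was at −1.17 (adjusted p = 0.47) and Vmn2r3 at 9.22 (adjusted p = 0.055). The largest single rise was of Vmn2r3, annotated as a vomeronasal receptor, which had 5 counts in the 6 controls together and 4823 in the 6 DKO libraries.

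With edgeR, 3053 of 17352 genes passed at labelled day 1, 1702 up and 1351 down in DKO, of which 446 and 107 changed more than 2-fold. Protein-coding genes made up 881 of the rises and 1193 of the falls. Of 1594 pseudogenes tested, 757 rose and 26 fell, and leaving them out moved the count to 1929 genes. Camera called 15 of 53 lists, and 0 were called with an estimated correlation (4 lists at an unadjusted p under 0.05), while fry called 17. The exact permutation test of list means called 12 lists, among them the integrated stress response (1.23), calcium handling (−0.36), ion channels (−0.35), p53 and apoptosis (0.22), mitochondrial chaperones (0.14) and cardiac stress (0.40, adjusted p = 0.0382). Schwann cell and nerve markers were called by the same test (−0.303, adjusted p = 0.0313). The calcium handling mean includes the atrial gene Sln, at −4.54, or −1.17 without the controls over 50 CPM of Myl7. Among the named genes, calls were lost for Ccn2, Myom2 and Kif5c with atrial transcripts as a covariate, for Nebl, Ttn and Thrb with the length trend removed, for Acot2 with all 24 libraries in 1 fit, and for Sln and Vmn2r3 with limma-voom. Thrb was lost without 8 of the 12 single libraries and Kif5c without 5.

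At labelled day 7 the integrated stress response was again the list with the most members past the threshold. Slc7a3 rose from 0.376 to 24.6 CPM (log2 fold change 6.02 ± 0.24, SE, n = 6, adjusted p = 5.4e-10), and Asns rose from 12.9 to 143 CPM (3.45 ± 0.13). Phgdh rose by 3.06 ± 0.09, Mthfd2 by 2.84 ± 0.16 and Trib3 by 4.37 ± 0.25. Chac1, which degrades glutathione, rose by 5.99 ± 0.32, and the stress gene Nupr1 rose by 3.62 ± 0.23. Pycr1, the last enzyme of proline synthesis, rose by 1.88 ± 0.14, Sesn2 by 1.54 ± 0.14, Atf5 by 1.82 ± 0.09 and Atf4 by 0.81 ± 0.12. Gdf15 rose by 2.93 ± 0.53 (adjusted p = 0.020), and Fgf21 went from 2 counts in the 6 controls to 453 in the 6 DKO libraries, a ratio of 211 (95% Clopper-Pearson interval for counting error, 58.0 to 1744). Of 40 members, 29 rose and 0 fell, or 33 rose and 0 fell adjusted over the list alone, with 0 falls at an unadjusted p under 0.05 and 32 rises and 0 falls with DESeq2 and with limma-voom. The median was 0.84, and this list kept its call with an estimated correlation (adjusted p = 3.7e-05). The exact permutation test of its mean gave a difference of 1.54 with p = 0.0021645, the smallest possible, and an adjusted p = 0.115, the value a list at the smallest possible p gets over 53 lists when no other list lowers it, so it could not have passed alone.

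A few genes of calcium handling and of the sarcomere and its anchors fell at labelled day 7. Atrial markers were higher in these DKO libraries, by 0.735 in the mean of their list (exact permutation test, adjusted p = 0.284). For that list, 5 of 6 DKO libraries were above the control mean. Fewer genes passed with atrial transcripts as a covariate or without m1124 and m1128, as given with the processing. Cacna1c, the pore of the L-type calcium channel, fell from 2046 to 1531 CPM (−0.43 ± 0.06, adjusted p = 0.0012), and Cacnb2 fell by 0.43 ± 0.09. Ryr2 was at −0.49 ± 0.11 and did not pass (adjusted p = 0.06). The calcium handling list had 0 of 26 genes up and 3 down, or 6 down adjusted over the list alone, and kept its call with an estimated correlation (median −0.12, adjusted p = 0.0133). The exact permutation test of its mean over libraries gave a difference of −0.0256, with 3 of 6 DKO libraries above the control mean (adjusted p = 0.795), and did not call the list. That mean includes the atrial gene Sln, at 140 and 67.5 CPM in DKO m1124 and m1128 against 0.365 to 16.2 CPM in controls. It therefore carries the atrial difference as well, and a mean without Sln was not tested. Its member Cmya5, which codes for a protein near the Z-disc and the calcium release units, fell by 0.58 ± 0.08. Trim55, a ubiquitin ligase of the sarcomere, and Palld fell by 0.39 ± 0.06 and 0.43 ± 0.07. Of 48 sarcomere genes, 1 rose and 3 fell, or 3 rose and 10 fell adjusted over the list alone (median −0.11, camera adjusted p = 0.0011, adjusted p = 0.332 with an estimated correlation). Itgb1bp2, which codes for the integrin-binding protein melusin, fell by 0.53 ± 0.07, Ctnna3 by 0.40 ± 0.08 and the talin gene Tln2 by 0.38 ± 0.08. The intercalated disc and costamere list had 0 of 32 genes up and 3 down, or 4 down adjusted over the list alone (median −0.13, adjusted p = 0.226 with an estimated correlation). Neither this list (−0.126, adjusted p = 0.138) nor the sarcomere list (−0.0735, adjusted p = 0.194) was called by the exact permutation test. The muscle coactivator Myocd fell by 0.38 ± 0.08. The cardiac myosins were at −0.05 ± 0.11 (Myh6, adjusted p = 0.89) and −0.26 ± 0.16 (Myh7, adjusted p = 0.49).

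A few genes of mitochondrial protein care rose at labelled day 7 as well. Hspa9 rose by 0.40 ± 0.05 (adjusted p = 0.0004), Chchd10, a protein of the intermembrane space, by 0.37 ± 0.07 and Lonp1 by 0.60 ± 0.11. Their list had 3 of 38 genes up and 0 down, or 8 up and 1 down adjusted over the list alone (median 0.06, adjusted p = 0.628 with an estimated correlation, and 0.114 with adjusted p = 0.138 by the exact permutation test). Fatty acid oxidation had 0 of 31 genes past the threshold with edgeR, 3 at an unadjusted p under 0.05, 0 with DESeq2 and 1 rise with limma-voom. Respiratory complex I had 0 of 34 genes with edgeR, 2 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom. Of the cardiac stress list, 1 of 27 genes rose, Uck2, a uridine kinase, by 0.47 ± 0.09 (adjusted p = 0.628 for the list with an estimated correlation). Nppa was at 1.10 ± 0.37 (adjusted p = 0.21), Nppb at 0.78 ± 0.44 (adjusted p = 0.46) and Ankrd1 at 0.72 ± 0.22 (adjusted p = 0.16). Ftcd, which links histidine breakdown to folate, fell by 0.69 ± 0.10, the RNA-binding gene Rbfox1 by 0.72 ± 0.15, and Igf2, a fetal growth factor, by 0.37 ± 0.08. Plekhh1 fell by 1.09 ± 0.20 (adjusted p = 0.017). Without the 4 libraries with Y transcripts, where fewer libraries are compared, the calls of Cacna1c, Cacnb2, Trim55, Palld, Ctnna3, Tln2, Myocd, Chchd10, Lonp1, Uck2, Ftcd, Rbfox1, Igf2 and Plekhh1 were lost with the direction kept. Single libraries also ended calls: Plekhh1 without m1124 (adjusted p = 0.053), Gdf15 without control m1064 or m1066 (adjusted p = 0.063 and 0.055), and Rbfox1, Cacnb2, Ctnna3, Tln2, Myocd, Uck2 and Igf2 without m1124 or m1128, among others (adjusted p up to 0.11).

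With edgeR, 177 genes passed at labelled day 7, 119 up and 58 down, of which 47 and 5 changed more than 2-fold. Without m1124 the count was 104, without m1128 109 and without m1026 302. It was 514 with DESeq2 and 677 with limma-voom. Camera called 17 of 53 lists, of which the integrated stress response and calcium handling kept their calls with an estimated correlation, and fry called 7. The exact permutation test of list means called 0 of 53 lists, with 13 lists at an unadjusted p under 0.05. Given the number of splits, a list at the smallest possible p could not pass over 53 lists without others near it.

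**Figure D2:**
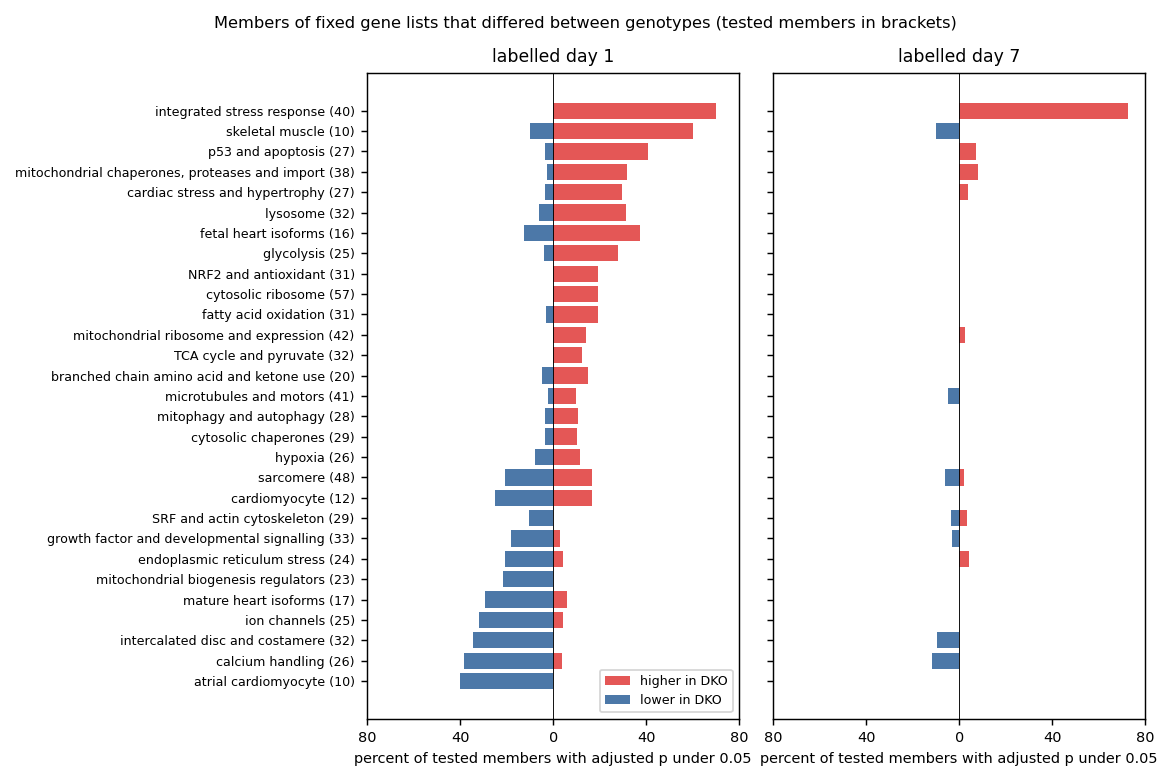
Percent of the tested members of each fixed gene list with an adjusted p under 0.05 in DKO against control, higher (red) or lower (blue), at labelled day 1 (left) and day 7 (right), for lists with at least 4 such members. Of 40 integrated stress response genes, 28 rose at labelled day 1 and 29 at labelled day 7.

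The genotype effects at the labelled ages shared direction. Of the 119 genes that rose at labelled day 7, 103 also rose at labelled day 1, where 11.7 would fall by chance (Fisher's exact test, two-sided, p = 4.6e-87). Of the 58 that fell, 42 also fell at labelled day 1, where 4.52 would fall by chance (p = 3.5e-34, Fisher's exact test). Both tests count genes, which are not independent replicates, so these p-values do not measure the spread between libraries. Together these 145 genes became 92 without m1124 and 221 without m1026, and 361 with DESeq2 and 424 with limma-voom. No gene passed in opposite directions. Asns, Phgdh, Mthfd2, Trib3, Slc7a3, Atf4, Lonp1 and Hspa9 were among the shared rises, and Palld, Cacnb2, Ctnna3 and Myocd among the shared falls. Genes that rose at labelled day 7 had a median log2 fold change of 0.75 there and 0.76 at labelled day 1, and genes that fell had −0.45 and −0.42. Across all 17352 genes, which are not independent replicates, Spearman's rho between the fold changes was 0.41.

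**Figure D3:**
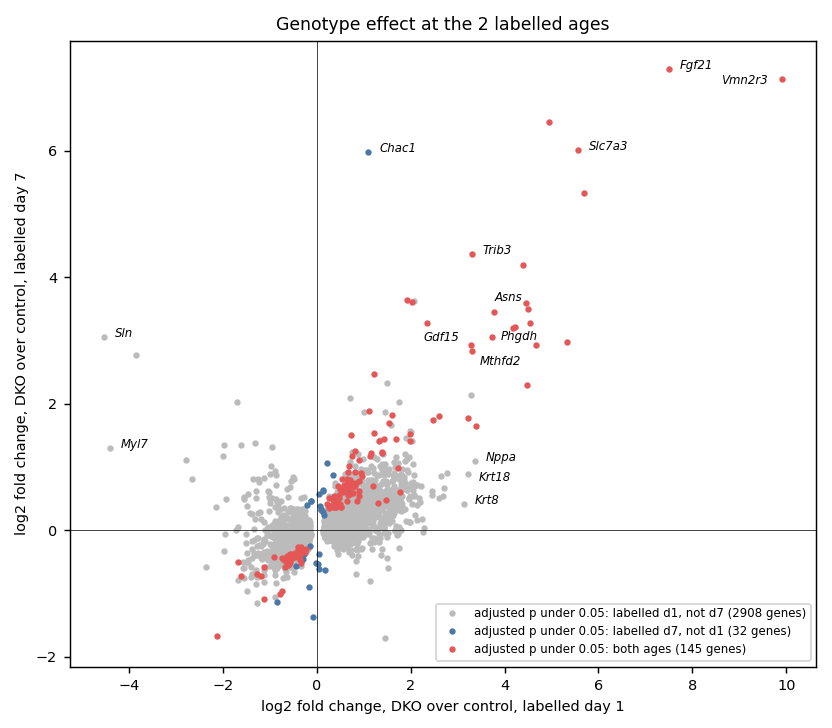
Log2 fold change of DKO over control at labelled day 1 (horizontal) and labelled day 7 (vertical) for genes with an adjusted p under 0.05 at labelled day 1 (grey), labelled day 7 (blue) or both (red). Of the 177 genes past the threshold at labelled day 7, 103 rises and 42 falls also passed at labelled day 1.

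The difference of the genotype effect between the labelled ages asks whether the response changes as the heart grows. Chac1 rose more at labelled day 7, by 4.90 ± 0.59 on the log2 scale (SE, adjusted p = 0.00018), with means of 3.88 and 8.35 CPM in controls and DKO at labelled day 1, and 0.171 and 11.3 CPM at labelled day 7. The keratins rose at labelled day 1 more than at labelled day 7, Krt18 with a difference of −2.32 (adjusted p = 0.0070) and Krt8 with −2.70 (adjusted p = 0.011). Prune2 followed the same direction, with a difference of −1.69 (adjusted p = 0.00052). Atrial transcripts differed most: Sln by 7.61 ± 1.65 (adjusted p = 0.028), Mybphl, a myosin-binding protein of atria and conduction tissue, by 6.64 and Myl7 by 5.73. Nppa had a difference of −2.26 (adjusted p = 0.14). In all, 54 genes had a more positive effect at labelled day 7 and 133 a more negative effect, of which 87 were pseudogenes. The counts over all genes were 364 with DESeq2, 549 with limma-voom, 55 without pseudogenes and 49 without m1124 and m1128. With only libraries that carry Y transcripts, 2 per group at labelled day 7, it was 250 with the balance turned, as 149 (59.6%) were more positive, and 89 of the 187 genes were among them. Leaving out 1 library gave from 90 genes (without m1124) to 287 (without control 13). Of 40 integrated stress response genes, 3 had a more positive effect at labelled day 7 and 0 a more negative one, or 7 and 0 adjusted over the list alone (adjusted p = 0.510 with an estimated correlation). The skeletal muscle list alone kept its call with an estimated correlation (median −0.92, adjusted p = 0.0253), with 3 of 10 genes more negative at labelled day 7, or 6 adjusted over the list alone. The calls of Sln and Myl7 ended without m1124 (adjusted p = 0.058 and 0.059) and without several other single libraries, and without m1124 and m1128 together.

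**Figure D4:**
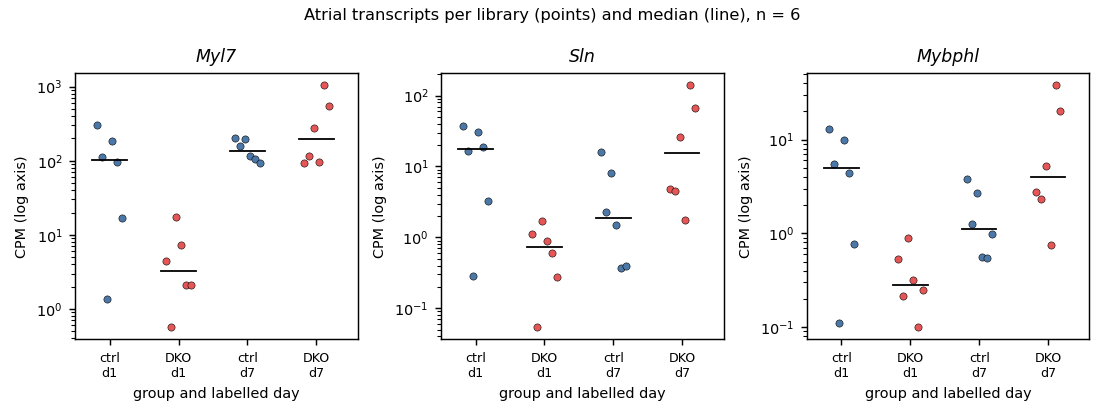
Levels (CPM, log axis) of the atrial transcripts Myl7, Sln and Mybphl in each library (points) with the median of each group (line, n = 6), in control (blue) and DKO (red) hearts at labelled day 1 and day 7. Myl7 was at 1.34 to 304 CPM in controls and 0.564 to 17.3 CPM in DKO at labelled day 1, and at 94.6 to 201 CPM and 94.5 to 1043 CPM at labelled day 7.

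Labelled age was compared within each genotype to ask how the heart changes over the first week. In controls, libraries labelled day 7 had more of the slow, fetal myosin Myh7 than those labelled day 1 (11787.5 against 2418.9 CPM, log2 difference 2.28 ± 0.13, SE, n = 6, adjusted p = 1.3e-12). They also had more Tnni1, fetal troponin I (1.65 ± 0.31), and less Tnni3, the adult form (−0.74 ± 0.10). Nppa was higher by 2.88 ± 0.53, while Myh6 was at −0.18 (adjusted p = 0.11). Fetal heart isoforms as a list had 11 of 16 genes up and 2 down at labelled day 7 (median 1.08, adjusted p = 0.249 with an estimated correlation). Mature isoforms had 2 of 17 up and 12 down (median −0.74, adjusted p = 0.249 with an estimated correlation). Genes of G2 and M phase were higher, 40 of 40 (median 1.09, adjusted p = 0.764 with an estimated correlation). Genes of complex I were lower, 33 of 34 (median −0.47, adjusted p = 0.312 with an estimated correlation), as were 23 of 31 genes of fatty acid oxidation (median −0.47, adjusted p = 0.465 with an estimated correlation). Adjusted over the list alone, these counts were the same except for 25 falls in fatty acid oxidation. In the known course of mouse heart development, Myh7, Tnni1 and cell division decline after birth while Tnni3 and oxidative genes rise, so these lists ran in the opposite order to the labels.

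Other cell types differed between the labelled ages too. Fibroblast markers were lower at labelled day 7, with 1 of 15 up and 13 down (median −1.18), a call kept with an estimated correlation (adjusted p = 0.0459). Endocardial markers were higher, 6 of 7 (median 0.35, adjusted p = 0.0459 with an estimated correlation). Lymphocyte and macrophage markers were lower, 7 of 9 and 13 of 16 (adjusted p = 0.584 and 0.375 with an estimated correlation), or 8 and 13 adjusted over the list alone. The largest single changes in controls were rises of Tent5b (5.95 ± 0.69) and Hif3a, a hypoxia-inducible factor (4.60), and falls of Mapt, the tau gene (−4.66 ± 0.26), and the tubulin gene Tuba8 (−4.51). After the values were seen, Igf2 and H19, imprinted fetal genes, were found higher by 1.76 and 2.34, and Cox8b and Cox7a1, muscle subunits of cytochrome oxidase, lower by 2.68 and 1.95. In all, 4757 genes were higher and 4449 lower at labelled day 7 in controls, and 4729 and 4390 in DKO. In DKO, Myh7 was higher at labelled day 7 by 1.88, Tnni1 by 1.84, and Tnni3 was lower by 0.56. The exact permutation test of list means called 26 of 53 lists in controls (12 up, 14 down) and 25 in DKO. Sequencing depth and, in part, Y transcripts changed with the label of age.

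Isoform pairs were compared because a heart that matures exchanges fetal for adult isoforms. The share of Myh6 in Myh6 plus Myh7 counts was 92.1 ± 0.67% in controls and 91.1 ± 0.45% in DKO at labelled day 1 (SD, n = 6), a difference of −0.995 percentage points (exact permutation test, p = 0.0173, adjusted p = 0.0693). In libraries labelled day 7 it was 67.8 ± 7.9% and 71.0 ± 5.6% (exact permutation test, adjusted p = 0.580). Myh7 had 75.3% of its exonic bases inside other genes against 3.26% for Myh6, so Myh7 may be undercounted. The Myh6 share is therefore compared only between groups and does not give the true isoform composition. The share of Tnni3 in Tnni3 plus Tnni1 was 80.1 ± 10.1% and 82.6 ± 6.5% at labelled day 1 (exact permutation test, adjusted p = 0.712). Among libraries labelled day 7 it was 43.4 ± 2.4% in controls and 47.0 ± 1.5% in DKO, a difference of 3.63 points with 6 of 6 DKO libraries above the control mean (exact permutation test, p = 0.0130, adjusted p = 0.0693). No genotype difference of the 8 tested passed after adjustment. For Cox8b in Cox8b plus Cox8a the differences were −5.03 and 1.84 points at the labelled ages (exact permutation test, adjusted p = 0.170 and 0.156). Some of the 8 passed when a single control was left out (exact permutation test, adjusted p = 0.0173), as given with the processing. Each share fell from labelled day 1 to labelled day 7 in both genotypes (exact permutation test, p = 0.0021645, the smallest possible). Of Cox8b plus Cox8a counts, Cox8b made 62.4 ± 6.3% in controls of labelled day 1 and 17.7 ± 1.9% in controls of labelled day 7.

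**Figure D5:**
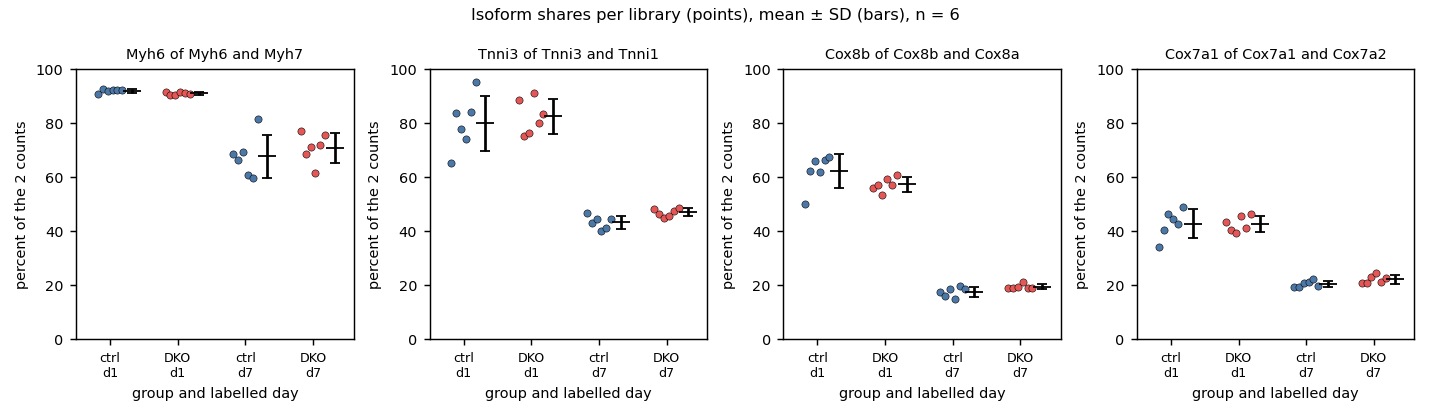
Share (percent) of the named isoform in the counts of 4 isoform pairs in each library (points), with mean and SD (bars, n = 6), in control (blue) and DKO (red) hearts at labelled day 1 and day 7. The share of Myh6 was 92.1% and 91.1% at labelled day 1, and 67.8% and 71.0% at labelled day 7. Myh7 counts may cover part of its transcript, so this share is compared only between groups.

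The position of DKO hearts along the change between labelled ages was measured with genes called in other controls, on a scale where a positive value points toward labelled day 7. At labelled day 1 the DKO libraries lay 0.0101 from controls, with 11 of 20 choices of controls positive and a range of −0.145 to 0.171. The median exact permutation p over the choices was 0.571. At labelled day 7 they lay at −0.0920, toward labelled day 1, with 2 of 20 choices positive, a range of −0.170 to 0.0385 and a median exact permutation p of 0.310. Of the 20 choices, 1 at labelled day 1 and 4 at labelled day 7 had an exact permutation p under 0.05. The median p passed the threshold at neither labelled age. For scale, with genes called in all controls, the mean position of controls was −0.653 at labelled day 1 and 0.913 at labelled day 7. The same controls called those genes.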

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

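The tests of the age labels, of processed pseudogenes and of atrial transcripts given here were chosen after the results were seen, while the counts of other splits of the libraries were planned before the data were examined. The rules for the verdicts on shared reads and on loss of atrial transcripts were rewritten after their first outcomes were seen. For shared reads the first rule had counted the excess of pseudogenes over parents as support, and the rule used here was set with these values known.

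Some libraries stood apart from the other 5 of their group. Control 13, labelled day 1, had 87.5 CPM of Nppa, 1849.5 CPM of Ankrd1 and 3.12 CPM of Gdf15, each the highest of its group. Control m1101, labelled day 7, had 482 CPM of Nppa. Control m1088, labelled day 7, had the lowest total, 17334498 counts, and 20538 detected genes. These were 6 of 88 groups of values examined by Dixon's test, where chance marks about 5%.

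The genotype effect differed between the labelled ages for 187 genes by the test of the difference itself. The named ones with a more positive effect at labelled day 7 were the atrial genes Sln (7.61), Mybphl (6.64) and Myl7 (5.73), the glutathione-degrading Chac1 (4.90) and Pdzrn4 (1.90), on the log2 scale. Those with a more negative effect were the keratin genes Krt8 (−2.70) and Krt18 (−2.32), Prune2 (−1.69), Bmp7, a growth factor of the bone morphogenetic family (−1.32), and Tmem116 (−1.19). Leaving out single libraries ended the call of Bmp7 without 17 of the 24, of Myl7 without 10, of Pdzrn4 without 9, and of Sln and Tmem116 without 5 each (adjusted p up to 0.071).

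Of 100 splits of the 12 libraries, 1 gave as many genes as the genotype at labelled day 1, the real one with 3053. The others gave at most 1 gene, and each of them mixed the genotypes. Chance is thus unlikely, at 1 in 100, the smallest share that these splits can show. For the genotype at labelled day 7, 1 of 100 did so, the real one with 177, against at most 1 gene in the others. For the difference between labelled ages, 1 of 100 regroupings gave 187 genes, the real one, and the others at most 0 with edgeR, where 1978 genes were at an unadjusted p under 0.05 in the real one, DESeq2 called 364 and limma-voom 549. For labelled age, 1 of 100 splits gave as many as the 9206 genes in controls, the others at most 5301, and 1 of 100 as many as the 9119 in DKO, the others at most 5054. Splits with that many genes point to the structure of labelled age, which most of them keep in part. For gene lists with the preset correlation, 63 of 100 splits gave at least the 15 lists of labelled day 1 (others at most 27), and 46 of 100 at least the 17 of labelled day 7 (others at most 25), so chance was not excluded for the number of lists.

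The fetal isoforms were higher and the mature isoforms lower in libraries labelled day 7, opposite to the known order of heart development. The medians of the fetal, mature and G2 and M phase lists were 1.08, −0.74 and 1.09 in controls and 1.01, −0.56 and 0.68 in DKO, and a candidate explanation is that the age labels of the library sets were exchanged. A sex difference does not account for it, since 107% of the difference between the fetal and mature medians stayed with only the libraries that carry Y transcripts. Other cell types are argued against for the isoform pairs taken to be made in the same cardiomyocytes. These pairs shifted by 2.43 (Myh7 to Myh6) and 2.60 (Tnni1 to Tnni3) on the log2 scale. The Tnni3 share also ranged from 65.4 to 95.1% among controls labelled day 1, so that pair varied within a group too. For the other members of the lists, other cell types were not tested and stay open. A library batch and labelled age cannot be told apart, as 0 sets of library names held both labelled ages, and age itself stays open as a biological difference.

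Processed pseudogenes and skeletal myosins were higher in DKO at labelled day 1, with a median of 0.45 over 1388 processed pseudogenes against 0.18 at labelled day 7. They took 2.51 ± 0.17% of counts in controls and 2.95 ± 0.07% in DKO (SD, n = 6), every DKO library above every control. Of the median, 81.5% stayed with the length trend removed. That trend was taken over genomic span, introns included, in protein-coding genes, so a bias with transcript length was not tested and stays open. Skeletal muscle tissue is argued against, since fast muscle genes other than myosins had a median of 0.17. Among them Actn3 was at 0.997 and Tnni2 at −0.75, while the myosins were at 1.70. Pseudogenes exceeded their parent genes by a median of 0.25, in 89.4% of 226 pairs, which a constant share of the parents' reads would not give. A share of reads that differs between libraries cannot be told apart from an effect of the deletion, since the treatment of reads matching several places was not given and the pseudogene share separates the genotypes at labelled day 1.

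Atrial transcripts differed strongly between libraries of one labelled age and genotype. A varying amount of atrial tissue in the dissected ventricle may account for it, since Myl7, Sln and Mybphl deviated from their group means together (lowest Pearson r = 0.876 with Spearman's rho = 0.883 over 24 libraries, permutation p = 1e-05 for both, the smallest possible, adjusted p = 1.67e-05 over 5 relations, r = 0.829 without the 2 libraries farthest from the median). Myl7 also ranged 226-fold among the controls labelled day 1. Loss of atrial transcripts with the deletion cannot be told apart from it: only 1 of the 6 DKO libraries labelled day 1 was below every control, and the mean of the 3 genes was −3.51 in DKO at labelled day 1 (exact permutation p = 0.0238) but 1.84 at labelled day 7 (exact permutation p = 0.0866). What keeps it open is that, in the mean of the 3 genes, the overlap at labelled day 1 rests on control 22. The reversal at labelled day 7 also did not pass the threshold. Taken singly, Myl7 and Mybphl were higher in DKO 35 than in control 62 too (17.3 against 16.9 CPM and 0.884 against 0.771 CPM).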

How the results depend on the processing

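Alternatives chosen after seeing the data were leaving out pseudogenes, removing the length trend, covariates of atrial or Y transcripts, and leaving out libraries with Y transcripts, controls with over 50 CPM of Myl7, or DKO m1124 and m1128; the others were planned. No paired analysis was possible because no replicate name was shared between groups.

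The genotype effect at labelled day 1 gave 1929 to 3667 genes over 11 alternatives, of which rises made up 53.1 to 63.8%. The lowest count came with pseudogenes left out (1929), where fewer genes are tested. Calls of genes still tested were lost as well, since 881 rises and 1193 falls of the main fit were protein-coding. Without each library in turn the genotype effect gave 2307 (without DKO 29) to 3624 genes (without control 13). At labelled day 7 the range was 66 to 677 genes, with 53.2 to 85.7% rises: 514 with the DESeq2 test, 677 with limma-voom, 419 with all 24 libraries in 1 fit, 76 with the atrial covariate, 66 without libraries with Y transcripts and 77 without m1124 and m1128. Without each library it gave 104 (without m1124), 109 (without m1128) to 302 (without m1026). The interaction gave 364 with DESeq2, 549 with limma-voom, 114 with no filter, 55 without pseudogenes and 49 without m1124 and m1128, with 16.3 to 59.6% of effects more positive, the highest with only libraries with Y transcripts (250 genes, 149 more positive, against 28.9% over all libraries). Without each library it gave 90 (m1124) to 287 (control 13), with counts moved by over 1.5 times also without controls 14 (118), 56 (108), m1022 (113), m1064 (92), m1066 (109) and m1091 (94), and without DKO 69 (108), 79 (113) and m1128 (111). Fewer libraries are compared when some are left out; for the other settings the cause was not tested. Labelled age gave 6427 to 9894 genes in controls and 6719 to 10015 in DKO, with 8618 to 9390 and 8576 to 9239 without each library.

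Camera's count of lists at labelled day 1 was 0 with an estimated correlation, 25 without pseudogenes and 13 to 17 without each library. The count at labelled day 7 was 2 with an estimated correlation and 16 to 21 without each library. The shared genotype effects numbered 361 with DESeq2 and 424 with limma-voom, against 92 (without m1124) to 221 (without m1026). The position along labelled age at labelled day 7 was −0.144 with all controls in both comparisons (exact permutation p = 0.0281, range of p over the alternatives in which a library was left out 0.170 to 0.420), where the same controls serve on both sides. It was −0.117 to −0.0729 without each library, and −0.00731 to 0.0358 at labelled day 1, where the sign turned without DKO 35 or DKO 69 (−0.00574 and −0.00731). With all controls in both comparisons the position at labelled day 1 was 0.0544 (exact permutation p = 0.519). With only genes changing at least 2-fold it was 0.0760 there, with 15 of 20 choices positive (median exact permutation p = 0.536). At labelled day 7 that setting gave −0.130 (median exact permutation p = 0.351).

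Isoform shares without each library moved from −1.26 to −0.885 points for Myh6 at labelled day 1 and from −7.44 to −4.03 for Cox8b, both at an exact permutation adjusted p of 0.0173 without control 13, and from −0.446 to 5.51 for Tnni3, negative without control 13. Cox7a1 moved from −1.93 to 1.07 and turned sign without controls 22, 25 and 62 or DKO 33, 35 and 69. The Tnni3 share at labelled day 7 moved from 3.01 to 4.29 (adjusted p = 0.0173 without m1022), Cox8b from 1.29 to 2.29 (0.0173 without m1091), Cox7a1 from 1.21 to 2.07 and Myh6 from 1.60 to 5.99. Among named genes, counting each alternative setting and, of the fits without each library, the lowest and highest fold change alone, the genotype effect at labelled day 1 kept its side of the threshold in 1806 comparisons, lost it in 133, gained it in 4 and turned in 4; at labelled day 7 these were 669, 114, 7 and 5. For the interaction 99 were kept and 21 lost, and for labelled age 164 and 1 in controls and 44 kept in DKO. With the atrial covariate Myl7 became 0.23, Mybphl 0.34 and Tnni1 0.00522 at labelled day 1; the covariate is the mean of Myl7, Sln and Mybphl, so their own values with it are near 0 by construction and say nothing about genotype. Tnni1 became 0.41 without the controls rich in Myl7. Ppargc1a at labelled day 7 became −0.177 with limma-voom and ranged from −0.0767 to 0.118 without each library. Tnni3 became 0.0295 without m1124 and m1128 and ranged from −0.0669 to 0.0541 without each library, and Myh6 from −0.109 to 0.0221; the cause was not tested. The depth, 17334498 to 45806171 counts per library, limits genes such as Fgf21 and Vmn2r3, with few counts in controls.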

Other observations

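The test of Rhot1 against the integrated stress response given here was chosen after the results were seen.

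Genes of mitophagy and autophagy had 3 of 28 members up and 1 down in DKO at labelled day 1, over all genes and adjusted over the list alone. Optn, an autophagy receptor for damaged mitochondria, rose by 0.96 ± 0.08 on the log2 scale in DKO at labelled day 1 (SE, n = 6, edgeR adjusted p = 2.1e-06), Sqstm1, the receptor p62, by 0.39 ± 0.07, and Gabarapl1, which marks autophagosomes, by 0.32 ± 0.07. Fundc1, a mitophagy receptor of the outer membrane, fell by 0.24 ± 0.05. Genes of the antioxidant response also rose in part, 6 of 31 with 0 falls by edgeR, both ways (1 lower at an unadjusted p under 0.05, and 8 rises and 0 falls with DESeq2 and limma-voom), among them Hmox1, heme oxygenase (0.71 ± 0.11), and Gpx4, which protects lipids from peroxidation (0.38 ± 0.06). Neither list was called by camera, while the exact permutation test of list means called the antioxidant list (0.12). Of 24 endoplasmic reticulum stress genes, 5 fell and 1 rose at labelled day 1, over all genes and adjusted over the list alone. Those that fell include the chaperone genes Hsp90b1 and Pdia6 (−0.19 ± 0.06 and −0.21 ± 0.07), and Ern1, the sensor IRE1, rose by 0.34 ± 0.08. That list was called neither by camera nor by the exact permutation test (−0.0526, adjusted p = 0.237), and the calls of Hsp90b1 and Pdia6 were each lost without 10 of the 12 single libraries.

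Lists of cell division, matrix and macrophage genes were called at labelled day 7 by camera with the preset correlation and not with an estimated one. None of them was called by the exact permutation test of list means (G2 and M phase −0.420, adjusted p = 0.382; matrix 0.2996, adjusted p = 0.194; macrophage 0.282, adjusted p = 0.115). Of 40 genes of G2 and M phase, 0 passed with edgeR or adjusted over the list alone, 8 were lower at an unadjusted p under 0.05, 0 passed with DESeq2 and 6 fell with limma-voom (median −0.43, camera adjusted p = 1.45e-10, adjusted p = 0.628 with an estimated correlation). Bub1b, a checkpoint kinase of mitosis, was at −0.55 ± 0.19 (adjusted p = 0.21). The extracellular matrix list had 0 of 39 genes past the threshold with edgeR, 1 rise adjusted over the list alone, 14 rises and 1 fall at an unadjusted p under 0.05, and 3 and 5 rises with DESeq2 and limma-voom (median 0.21, adjusted p = 0.628 with an estimated correlation). The macrophage list had 0 of 16 genes with edgeR, 4 rises adjusted over the list alone, 7 at an unadjusted p under 0.05, and 3 and 2 rises with DESeq2 and limma-voom (median 0.28, adjusted p = 0.405 with an estimated correlation). The extracellular matrix gene Bgn was at 0.53 ± 0.13 (adjusted p = 0.069) and the complement gene C1qc of macrophages at 0.39 ± 0.11 (adjusted p = 0.11).

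DKO libraries differed in the levels of stress response genes. Of those labelled day 7, m1124 and m1128, the DKO libraries of that age with Y transcripts, had 18.99 and 21.3 CPM of Gdf15 against 3.59 to 6.21 in the other 4, and the highest means of the integrated stress response list (5.72 and 5.69 log2 CPM). The same libraries had the most atrial transcripts of their group, with 1043 and 548 CPM of Myl7 against 94.5 to 273 in the other 4 and 140 and 67.5 CPM of Sln against 1.77 to 26.1. They also had 999 and 840 CPM of Nppa, which atrial muscle makes too. Trib3 was highest in m1124 and m1128 as well, at 102 and 85.2 CPM. Not every member of the stress response list followed: Mthfd2 and Phgdh were highest in m1092, at 146 and 156 CPM. Those genes were at 117 and 142 CPM in m1124 and at 136 and 153 CPM in m1128. At labelled day 1, DKO 79 had the lowest mean of the list (4.77) and the highest Rhot1 (136 CPM).

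A hypothesis was that DKO hearts with less Rhot1 RNA have a stronger stress response. Over the 12 DKO libraries, as deviations from group means, Pearson's r was −0.532 (permutation p = 0.0754, adjusted p = 0.0943 over 5 relations) and Spearman's rho −0.441 (permutation p = 0.153, adjusted p = 0.192). Without DKO 79 and m1046, the libraries farthest from the median of Rhot1, r was 0.00828, so the relation rests on them. In the 12 controls r was −0.0123 (permutation p = 0.97) and rho −0.175 (permutation p = 0.586), and r was −0.590 without controls 13 and m1022, so DKO and controls are not shown to differ in this relation. The extent of Rhot1 loss may set the strength of the response, but counts in tissue are not a direct measure of that loss. With 12 libraries the relation did not pass and cannot be told apart from the spread between libraries.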
